A study of Drosophila melanogaster with 7 samples.

How the data were processed

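Eye imaginal discs were profiled on 7 2-colour arrays, 4 for sevd2 and 3 for sevS11, each against a common pool of wild-type RNA. Per the labels, RNA was amplified and coupled to Cy3 or Cy5, and the arrays of a pair held the same RNA with the dyes swapped; sevS11 extraction 2 had a single unswapped array. The authors deposited normalised values per probe, taken here as log2 ratios; limma is named in the submitters' processing notes, and base 2 follows its convention. The background correction, normalisation, filter, log base and direction are not given in the sources used here. The deposited ratios were already turned to 1 direction, since the arrays of the 3 swapped pairs correlated at 0.777 to 0.939 across probes. Mutant over reference is the likely direction, because sev lay above 0 on the 3 sevS11 arrays and below 0 on the 3 sevd2 arrays with a value. Array medians were 0.0149, 0.0061, 0.0025 and 0.0012 for sevd2 and 0.0086, 0.0117 and 0.0191 for sevS11, and no further centring was applied.

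The table held 16416 probes, of which 8650 had no value on any array and 3064 had one on all 7. Probes were named from the platform annotation, which can be old, updated through the Release 6 plus ISO1 MT gene table, used for names and neighbours only. Of the probes, 12533 matched by gene identifier and 120 by accession, 511 kept the older symbol, 101 listed several genes and were not named, and 3151 were not listed. The probes of a gene were averaged, which applied to 246 genes. Of 5973 genes with a value, the 3587 with one from every extraction were tested.

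The replicate was the RNA extraction, and the arrays of an extraction were averaged. The labels do not say whether the extractions came from separate animals, so p-values measure only the spread between extractions, which may be technical. For the unswapped array the dye effect per gene, the mean over the 3 swapped pairs, was subtracted. The 147 tested genes with no complete pair were not corrected. Most of these pairs were of sevd2. Across genes the dye effect correlated at 0.326 with the mean sevd2 ratio and at 0.114 with the ratio of sevS11 extraction 1. The correction may therefore have carried some of the sevd2 signal into sevS11 extraction 2. The 4 extractions were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, prior degrees of freedom 3.8, residual 2), with a mean per genotype and 1 shared spread. The 3 contrasts were each genotype against 0 and sevS11 minus sevd2, at a Benjamini-Hochberg adjusted p under 0.05.

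The design, the 25 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named sev, the 10 largest rises and 10 largest falls among genes that passed with 1 sign on every array, filled where fewer passed with the largest changes that did not pass, and up to 4 members per list by lowest p. Spn47C in sevS11 falls outside the rule and was named after its value was seen, as a gene passing in both genotypes. Camera with a preset correlation of 0.01 tested the 15 lists with at least 5 tested genes, adjusted within a contrast, beside camera with an estimated correlation and fry. With an estimated correlation camera tests on the 2 residual degrees of freedom, so hardly any shift could pass. Not passing there says little for or against a list. The simulation described below tested lists only with the preset correlation. The other 10 lists are given as medians over members with a value. The lists overlap in part, and phyl is on 3 of them.

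The steps were tested on 20 simulated data sets of 3587 genes, with 200 genes changed in each. For sevS11 against the reference 63.1% of changes of 0.5 (log2) and 99.8% of changes of 1 were recovered, and 7.71% of calls were false. These were 59.6%, 99% and 4.62% for sevd2 and 21.4%, 94% and 6.92% for sevS11 minus sevd2. The simulation drew normal noise with 1 spread per gene for both genotypes and none for the reference. In the data the smallest absolute log2 ratio that passed was 0.461 in sevS11, 1.286 in sevd2 and 2.102 in sevS11 minus sevd2. The recovered shares therefore do not give the power in these data, and genes that did not pass may have changed. The alternatives covered the dye correction, an array-level fit, the genotype's own extractions, centring, scaling to 1 median absolute value, quantile normalisation, weights, a robust fit, complete genes, single probes, the threshold, a block on the extraction number, the list tests and leaving out each array and extraction.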

Results

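Gene expression was compared on 2-colour arrays in eye imaginal discs, the larval epithelia from which the compound eye forms. The discs came from Drosophila melanogaster carrying an altered form of sevenless (sev). Sevenless is the receptor tyrosine kinase that directs the R7 photoreceptor fate. The allele sevd2 is known as a loss-of-function allele and sevS11 as an activated form of the receptor. RNA of each genotype came from 2 extractions and was hybridised against a common reference pool of w1118 wild-type discs. There were 4 arrays for sevd2, a dye-swapped pair per extraction, and 3 for sevS11, a dye-swapped pair for extraction 1 and a single array for extraction 2. Values were present for 4701 to 5691 probes per sevd2 array and for 5194 to 7009 probes per sevS11 array, and the number of arrays limits the precision. Values are given as log2 ratios, likely of mutant over reference, with the standard error (SE) of the limma fit, whose spread was shared by both genotypes, over n = 2 extractions each. The tests against the reference leave out the control's own spread.

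The sev transcript itself was 3.14 ± 0.54 (log2 ± SE) above the reference in sevS11 (limma, adjusted p = 0.0367), with 1.85 in extraction 1 and 4.43 in extraction 2. In sevd2 the sev ratio was -0.36 ± 0.54 and did not pass (limma, adjusted p = 0.904), with extraction values of -0.32 and -0.41. The difference between the genotypes, 3.50 ± 0.77, did not pass either (limma, adjusted p = 0.186). The sevS11 call ended without sevS11 replicate 1 at 3.12 (limma, adjusted p = 0.0575), and without sevS11 replicate 3, the only array of extraction 2, the value was 1.85. Without that array the sevd2 ratio was -0.36 and the difference 2.21, and without sevS11 extraction 1 they were -0.36 and 4.84. The difference was 3.52 without sevd2 extraction 1 and 3.46 without sevd2 extraction 2. Each of these fits left a single extraction in 1 genotype, so only effect sizes are given for them. The likely direction of the ratios was itself taken from sev, so the sev values do not check the labels. Where the sev probe lies relative to the change in either genotype is also not known here.

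In sevS11 eye discs 78 genes were higher and 129 lower than in the reference, of 3587 tested. Besides sev, the 9 largest rises were those of CG32207 (2.39 ± 0.10), CG18294 (2.02 ± 0.09), Obp99a, an odorant-binding protein gene (2.00 ± 0.21), the prophenoloxidase gene PPO2, a product of crystal cells in the blood (1.75 ± 0.12), the glutathione S-transferase gene GstE1 (1.66 ± 0.22), CG17681 (1.65 ± 0.10), the metallothionein gene MtnA (1.63 ± 0.29), the RNA-binding protein gene Syp (1.30 ± 0.14) and He, which encodes a surface protein of blood cells (1.26 ± 0.18). Of the genes that passed, the ribosomal protein gene RpS21 had the largest fall (-2.34 ± 0.22). It was followed by CG6959 (-1.96 ± 0.12), CG18853 (-1.94 ± 0.15), CG4250 (-1.58 ± 0.22), the endonuclease G inhibitor gene EndoGI (-1.49 ± 0.14), CG7900 (-1.48 ± 0.13), the sodium/proton exchanger gene Nhe2 (-1.39 ± 0.14), the MAP kinase kinase kinase gene wnd (-1.36 ± 0.10), the cytochrome P450 gene Cyp9c1 (-1.33 ± 0.18) and kek5, of the kekkon family of transmembrane proteins (-1.32 ± 0.21). In limma's test the adjusted p of these genes lay between 0.00174 and 0.0380, and all 207 genes had the same sign on every sevS11 array with a value. The largest ratios were not all particular to sevS11. The ratios of CG32207, CG18294, GstE1, CG17681, Syp, RpS21 and CG18853 had the same sign in sevd2, as given below. Those of PPO2 and He had the opposite sign there. Without the dye correction the calls of MtnA (1.62, adjusted p = 0.0506) and He (1.15, adjusted p = 0.0552) ended. The count of 207 became 117 (46 higher, 71 lower) with scaling, 132 for genes on every array and 395 (160 higher, 235 lower) in the array-level fit. It was 76 without sevS11 replicate 1. Counts are not given for fits that left a single extraction in 1 genotype, where the spread came from the other genotype alone. With arrays left out the genes tested also changed, since each needed a value in every extraction left.

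**Figure D1:**
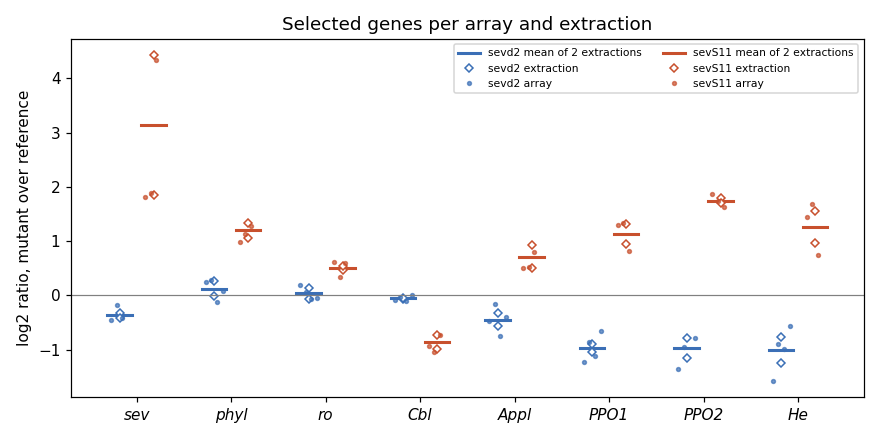
Log2 ratio of mutant over reference (vertical axis) for 8 genes in sevd2 and sevS11, with dots for arrays, diamonds for extractions and bars for the mean of 2 extractions. PPO1, PPO2 and He lie at -0.97, -0.97 and -1.01 in sevd2 and at 1.13, 1.75 and 1.26 in sevS11, and the sevS11 extractions of sev lie apart at 1.85 and 4.43.

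Genes of the receptor pathway and of photoreceptor fate were among the genes that passed in sevS11. Of 13 tested genes of the Sevenless, Ras and MAPK pathway, 2 rose, namely sev and phyl, which encodes an adaptor for the degradation of Tramtrack (1.20 ± 0.12), and 1 fell, the ubiquitin ligase gene Cbl (-0.86 ± 0.11). Among 6 R7 and R8 fate genes, phyl and ro, a homeobox gene of photoreceptor specification (0.51 ± 0.10), rose. Of 6 photoreceptor and neuronal differentiation genes only Appl, the amyloid precursor-like gene of neurons, passed (0.72 ± 0.14), while Rop stood at -0.51 ± 0.11, chp at -0.46 ± 0.11 and nrv3 at 0.43 ± 0.10. Of 11 EGFR ligand and MAPK-induced feedback genes only phyl passed, and the feedback inhibitor gene sty stood at 0.57 ± 0.12 (limma, adjusted p = 0.0568). Adjusted over the list alone, 2 genes were higher and 1 lower in the pathway list, 2 and 1 in the R7 and R8 list, 3 and 2 in the neuronal list and 2 and 0 in the feedback list. None of these lists passed as a whole (camera, adjusted p from 0.105 to 0.722). The sevS11 extraction means of the photoreceptor and neuronal list had opposite signs, at -0.12 and 0.24. The call of ro ended without sevS11 replicate 1 (0.47), sevd2 replicate 4 (0.49), sevd2 extraction 1 (0.51) or sevd2 extraction 2 (0.49), and that of Appl without sevS11 replicate 1 (0.66). Both also ended without the dye correction (ro 0.54, Appl 0.66), with scaling (ro 0.39, Appl 0.56) and with quantile normalisation (ro 0.39, Appl 0.53), and ro with only the sevS11 extractions, in a robust fit and per probe (0.51 in each) and with the sevS11 pair's dye effect (0.47).

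Notch targets and other genes of the morphogenetic furrow, the moving front of differentiation in the eye disc, were higher in sevS11 as a list in camera with its preset correlation (adjusted p = 0.000571), but not with an estimated correlation (adjusted p = 0.867) or in fry (adjusted p = 0.128). Their mean was 0.33 over 13 tested genes, with 0.29 and 0.36 in the extractions, and 11 members lay above 0. The Bearded-family genes E(spl)m4-BFM (0.83 ± 0.10) and E(spl)malpha-BFM (0.51 ± 0.09) and the bHLH repressor gene E(spl)mdelta-HLH (0.54 ± 0.10) rose, 10 members did not pass, and 5 were higher when adjusted over the list alone. Without sevS11 replicate 1, sevd2 extraction 1 or sevd2 extraction 2 the calls of E(spl)malpha-BFM (0.51, 0.52 and 0.51) and E(spl)mdelta-HLH (0.54, 0.55 and 0.53) ended. So they did with scaling (0.37 and 0.41), quantile normalisation (0.37 and 0.44) and only the sevS11 extractions (0.51 and 0.54), and E(spl)mdelta-HLH without the dye correction (0.48).

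Of the hemocyte genes, which mark blood cells, PPO1 (1.13 ± 0.12), PPO2 and He rose in sevS11 and 5 others did not pass, among them the collagen gene Col4a1 (0.37 ± 0.10). Adjusted over the list alone, 4 were higher. The list mean was 0.52 and the median 0.22 over 8 tested genes, and the list did not pass (camera, adjusted p = 0.0549). With all arrays the adjusted p was 0.867 with an estimated correlation and 0.128 in fry. With the preset correlation the list passed without sevd2 replicate 2 (0.60, camera adjusted p = 0.0113) or sevS11 replicate 2 (0.68, camera adjusted p = 0.0383). In the first of these fits NimC1 had no value left in sevd2 extraction 1 and was not tested. In the second the same held for ush in sevS11 extraction 1. These means therefore do not cover the same genes as the mean of 0.52. With a single sevd2 extraction left, the mean was 0.44 without extraction 1 and 0.52 without extraction 2.

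The remaining lists did not pass in sevS11 (camera, adjusted p from 0.693 to 0.801). In the cell death and stress kinase list the initiator caspase gene Dronc fell (-1.06 ± 0.12) and 5 members did not pass. Of 14 ribosomal protein genes, RpLP1 rose (0.63 ± 0.12) and RpS21 fell, and the mean of this list was -0.06 while its median was 0.14, with camera's direction up and fry's down. The RpLP1 call ended without sevS11 replicate 1 (0.53), sevd2 replicate 2 (0.60) or sevd2 extraction 1 (0.60), with scaling (0.47), quantile normalisation (0.50), the array-level fit (0.65) or the sevS11 pair's dye effect (0.53). No member passed among 5 cone and pigment cell genes, 10 retinal determination genes, 5 glial genes, 7 tracheal and peripodial genes, 14 cell cycle genes, 6 heat shock genes and 7 ecdysone response genes (limma). At an unadjusted p under 0.05 these lists held 3, 1, 0, 4, 2, 1 and 2 genes, and their means were 0.09, 0.08, -0.15, -0.16, 0.03, 0.10 and -0.20. The ecdysone-inducible genes ImpE2 and ImpE3 stood at -1.29 ± 0.28 and -0.65 ± 0.13, and the extraction means of the ecdysone list were -0.67 and 0.26. The extraction means also had opposite signs for heat shock (-0.26 and 0.46), retinal (-0.12 and 0.27), tracheal and peripodial (-0.35 and 0.04), cell death (-0.35 and 0.07) and ribosomal protein genes (0.19 and -0.31). The ecdysone list had a median of 0.05, opposite to its mean, and the cell cycle list one of -0.01. Adjusted over the list alone, the remaining lists held 2 lower ecdysone genes, 1 higher and 2 lower ribosomal protein genes, 1 higher and 1 lower tracheal and peripodial genes, and 1 lower cell death gene. The furrow list was the only one of 15 that passed camera with the preset correlation (adjusted p = 0.867 with an estimated correlation), and 0 with an estimated correlation and 0 in fry passed (0 and 2 at an unadjusted p under 0.05). With the preset correlation 2 passed without sevd2 replicate 2, sevS11 replicate 2 or sevS11 replicate 3, 3 and 5 without sevd2 extractions 1 and 2 and 4 without sevS11 extraction 1.

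In sevd2 eye discs 3 genes passed against the reference, a count that became 174 (74 higher, 100 lower) with scaling, 166 (75 higher, 91 lower) with quantile normalisation and 39 (9 higher, 30 lower) in the array-level fit. CG32207 (1.56 ± 0.10) and CG18294 (1.29 ± 0.09) were higher and the serpin gene Spn47C was lower (-1.66 ± 0.14), with limma adjusted p of 0.0226, 0.0226 and 0.0315. Among the lowest ratios that did not pass were those of RpS21 (-2.22 ± 0.22), pst (-1.49 ± 0.20), CG18853 (-1.40 ± 0.15), the imaginal disc growth factor gene Idgf6 (-1.35 ± 0.15), lectin-28C (-1.27 ± 0.20), the receptor pseudokinase gene otk (-1.26 ± 0.14), He (-1.01 ± 0.18) and Had2 (-1.01 ± 0.13). Among the highest were those of Syp (1.28 ± 0.14), GstE1 (1.12 ± 0.22), CG17681 (1.04 ± 0.10), ana (0.92 ± 0.11), Jhbp2 (0.89 ± 0.30), the Golgi matrix gene GM130 (0.84 ± 0.15) and Acat1 (0.83 ± 0.12). At an adjusted p threshold of 0.1 the count was 33, and 351 genes had an unadjusted p under 0.05. Without the dye correction limma called 0 genes, with 333 at an unadjusted p under 0.05. The 3 genes then stood at 1.56, 1.29 and -1.66 as with the correction, which altered only sevS11 extraction 2 (limma, adjusted p = 0.0728 for each). With only the sevd2 extractions in the fit limma called 497 genes, on the spread of these 2 extractions alone, and such calls are not firm. The count was 22, 17 and 18 without sevd2 replicates 2, 3 and 4, and 7 and 9 without sevS11 replicates 1 and 2. Without sevd2 extraction 1, which left a single sevd2 extraction, CG18294 stood at 1.26.

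Hemocyte genes were lower in sevd2 as a list, the only list of 15 that passed camera with the preset correlation (adjusted p = 0.815 with an estimated correlation). Their mean was -0.57 over 8 tested genes, with -0.63 and -0.50 in the extractions. No member passed over all genes (limma; 5 at an unadjusted p under 0.05), the lowest p values being those of PPO2 (-0.97 ± 0.12), PPO1 (-0.97 ± 0.12), the matrix protein gene SPARC (-0.79 ± 0.12) and He. Adjusted over the list alone, 5 were lower. The adjusted p was 1.27e-06 in camera with the preset correlation, and the list did not pass in fry (adjusted p = 0.190). The other 14 lists had camera adjusted p from 0.123 to 0.973 and no member passing over all genes (limma; 0 to 2 per list at an unadjusted p under 0.05); furrow and Notch target genes had a mean of 0.04 and the Sevenless pathway genes 0.02. Adjusted over the list alone, 1 tracheal and peripodial gene was higher and 1 ribosomal protein gene lower, and glial genes had a mean of 0.00 and a median of -0.07. The count of 1 list, which was 0 with an estimated correlation and 0 in fry (0 and 1 at an unadjusted p under 0.05), was with the preset correlation 2 without sevd2 replicate 3, sevS11 replicate 3 or sevS11 extraction 1 and 8 without sevd2 extraction 2.

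**Figure D2:**
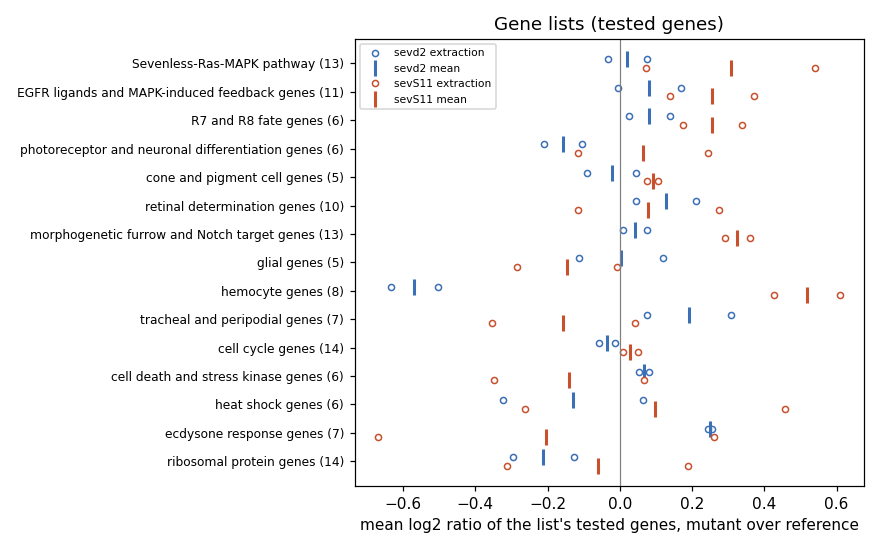
Mean log2 ratio over the tested genes of each of 15 lists, given for each extraction and as the mean of 2 extractions per genotype. Hemocyte genes lie at -0.57 in sevd2 and 0.52 in sevS11, and furrow and Notch target genes at 0.04 and 0.33.

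Set directly against each other, sevS11 and sevd2 discs differed in 2 genes, both prophenoloxidases and both higher in sevS11. The count became 27 (20 higher, 7 lower) with scaling, 23 (15 higher, 8 lower) with quantile normalisation and 41 (25 higher, 16 lower) in the array-level fit. PPO2 differed by 2.72 ± 0.17 (limma, adjusted p = 0.0180) and PPO1 by 2.10 ± 0.17 (limma, adjusted p = 0.0429). Above 0 without passing were He (2.27 ± 0.26), MtnA (2.01 ± 0.40), lectin-28C (1.80 ± 0.29), Obp99a (1.69 ± 0.30), otk (1.48 ± 0.20), Idgf6 (1.40 ± 0.21) and Had2 (1.32 ± 0.18). Below 0 without passing were Jhbp2 (-1.78 ± 0.42), ImpE2 (-1.54 ± 0.40), CG6959 (-1.47 ± 0.16), the glutamate transporter gene dmGlut (-1.40 ± 0.15), kek5 (-1.36 ± 0.29), obst-B (-1.30 ± 0.24), the sideroflexin gene Sfxn2 (-1.23 ± 0.13) and EndoGI (-1.19 ± 0.20). Of the eye genes, phyl differed by 1.08 ± 0.18, Cbl by -0.80 ± 0.15 and Appl by 1.16 ± 0.19, none of which passed. At an unadjusted p under 0.05 there were 458 genes. The PPO1 call ended without the dye correction (2.03, adjusted p = 0.145), with arrays centred (2.12, adjusted p = 0.0504), and without sevd2 replicate 1 (2.06), sevd2 replicate 3 (2.02) or sevS11 replicate 2 (2.23). It also ended in a robust fit, for genes on every array and per probe (2.10 in each, with limma adjusted p of 0.0520, 0.0561 and 0.0537). The same held with the sevS11 pair's dye effect (2.04). The dye effect correlated with the sevd2 ratios across genes, and its correction raised the PPO1 difference from 2.03 to 2.10. The count was 1 without sevd2 replicate 1 or 3 or sevS11 replicate 2, and 6 without sevd2 replicate 2. It was 1 without sevd2 replicate 4, where PPO2 had no value left in extraction 2 and was not tested.

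As a list, hemocyte genes were higher in sevS11 than in sevd2 by 1.09, with 8 of 8 members above 0 and 5 higher when adjusted over the list alone. The shift passed camera (adjusted p = 3.94e-06) but not with an estimated correlation (adjusted p = 0.826) or in fry (adjusted p = 0.121). The test with an estimated correlation had 2 residual degrees of freedom, so hardly any shift could pass it. Furrow and Notch target genes were higher by 0.28, with 12 of 13 members above 0 and 0 passing when adjusted over the list alone (limma; 3 at an unadjusted p under 0.05). This shift passed camera (adjusted p = 0.00412) but not with an estimated correlation (adjusted p = 0.826), in fry (adjusted p = 0.392) or without sevS11 replicate 3 (0.25, camera adjusted p = 0.127). The other 13 lists had camera adjusted p from 0.103 to 0.638; adjusted over the list alone they held 2 higher genes and 1 lower in the Sevenless pathway, 1 higher each in the feedback, R7 and R8 and neuronal lists, 1 lower each in the tracheal and cell death lists and 2 lower ecdysone genes. The R7 and R8 list had a mean difference of 0.17 and a median of -0.07. The count of 2 lists, which was 0 with an estimated correlation and 0 in fry (0 and 1 at an unadjusted p under 0.05), was with the preset correlation 4 without sevS11 replicate 3 or sevd2 extraction 1, 7 without sevd2 extraction 2 and 5 without sevS11 extraction 1.

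The 3 genes that passed in sevd2 passed in sevS11 in the same direction, Spn47C at -0.74 ± 0.14 there. Independent lists of these sizes would share 0.0435 higher and 0.0360 lower genes. Across the 3587 genes, which are not independent replicates, the ratios of the genotypes correlated at Pearson 0.332 and Spearman 0.239, with a covariance of 0.0225. Simulated unchanged genotypes that share a reference as variable as an extraction gave 0.668, 0.643 and 0.0330, and a mean of 55.9 genes passing in both. The observed minus the simulated covariance was -0.0105. The spread set for the simulated reference fixes the simulated correlation in advance, and the observed values lay below the simulated ones. The simulation therefore cannot say how much of the correlation comes from the reference or from shared effects. The reference was 1 pool that could not be split, so part of the overlap may come from it.

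**Figure D3:**
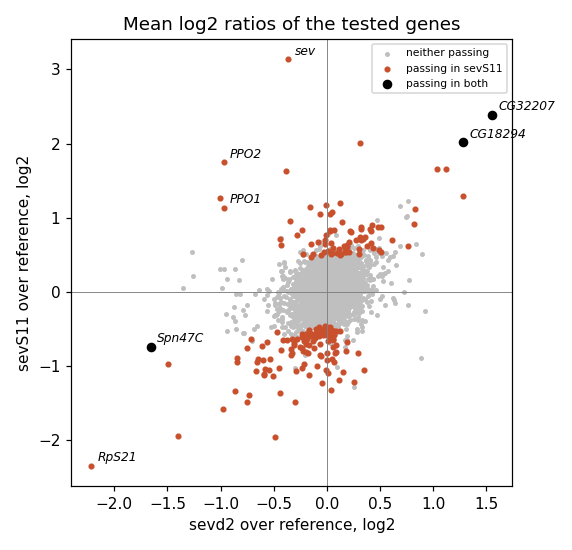
Mean log2 ratio over the reference in sevd2 (horizontal axis) and sevS11 (vertical axis), with a dot per tested gene, genes passing in sevS11 in red and those passing in both in black. PPO2 lies at -0.97 and 1.75 and CG32207 at 1.56 and 2.39.

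Most label fields describe the reference pool as eye discs and a free-text description as wing discs, so genes of both tissues were compared. Retinal determination genes, which specify eye tissue, had median ratios of 0.10 in sevd2 (-0.11 to 0.32) and 0.00 in sevS11 (-0.29 to 0.33) over 10 genes with a value. Wing disc genes had medians of -0.05 over 6 genes and -0.13 over 9 genes. The medians in sevd2 and sevS11 were 0.24 and -0.04 for antennal disc genes, 0.12 and 0.15 for larval brain neuroblast genes, 0.01 and 0.11 for fat body genes and -0.03 and 0.08 for muscle genes. They were 0.11 and 0.50 for cuticle genes, 0.09 and 0.31 for detoxification genes, -0.07 and -0.20 for eye pigment and marker genes and -0.05 and 0.09 for dosage compensation and sex genes. A single antimicrobial gene had a value, 0.11 in sevS11. These lists other than the retinal one had under 5 tested genes and were not tested.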

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

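All tests of explanations in this part were chosen after the results were seen; the differences between the genotypes were planned. Between the genotypes PPO2 differed by 2.72, PPO1 by 2.10 and the hemocyte list by 1.09, which passed camera with the preset correlation but not with an estimated correlation (adjusted p = 0.826) or in fry (adjusted p = 0.121). Dye bias is argued against, since the mean of the list's tested genes had its genotype's sign on 7 of 7 arrays, over both dye orientations. Plasmatocytes are the main blood cells, and their markers did not rise in sevS11 as PPO1, PPO2 and He did. Over 7 of 10 markers with values in both extractions the median was 0.051 (SD across markers 0.236). The lowest of PPO1, PPO2 and He was 1.13. The marker medians were 0.196 in extraction 1 and -0.128 in extraction 2. He, itself a blood cell gene, was set beside PPO1 and PPO2 and not counted as a marker. The test thus cannot decide whether sevS11 discs held more plasmatocytes. A narrower version with 4 markers in extraction 2 alone, chosen after their values were seen and then replaced, gave -0.194. The same markers gave 0.196 in extraction 1. Fewer plasmatocytes in sevd2 stay open, with a median of -0.404 over 4 markers (SD 0.299), as do crystal cells, since their regulator lz (0.622 in sevS11 and 0.427 in sevd2, in a single extraction each) is also on the R7 and R8 and the cone cell lists and cannot read crystal cell number in eye discs, and the genotype itself, which was not tested as an explanation.

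A second pattern is the genes changed alike in both genotypes. Of 17 genes with an adjusted p under 0.1 in sevd2 that passed in sevS11, 15 had the same direction. The shared reference pool and a difference between the wild-type and mutant strains both predict this, and they cannot be told apart with 1 reference pool and no wild-type sample. A response common to both genotypes stays open as well and was not tested.

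Probes without a listed gene, which no comparison used, carried signal. Of 1041 such probes tested singly with limma, 351 passed in sevS11 and 163 in sevd2, and 0 in the difference between the genotypes (504 at an unadjusted p under 0.05). A set of 146 lay above 1.5 in sevS11 and 0.5 in sevd2, with medians of 1.86 and 0.98. With the probe numbers divided into 48 blocks of 342, this set took up 11 places, against 75 to 107 in 1000 random sets of unlisted tested probes, which is consistent with spots repeated at fixed places of the print layout. What these spots hold is not known here, and no biological explanation was tested.

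The furrow and Notch target list differed between the genotypes by 0.28 (camera, adjusted p = 0.00412), but did not pass with an estimated correlation (adjusted p = 0.826), in fry (adjusted p = 0.392) or without sevS11 replicate 3 (0.25, camera adjusted p = 0.127). For Gasp the first sevd2 array, at 1.17, stood apart from the other 3 by Dixon's outlier test, as in 1 of 94 named genes with 4 sevd2 values. The test's rate of about 5% by chance assumes 4 independent values of equal spread. That rate does not apply here, since the arrays were dye-swapped pairs of the same extractions. The first array also had the widest SD across probes of the sevd2 arrays (0.41).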

How the results depend on the processing

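Every alternative but the dye effect from the sevS11 pair alone, chosen after seeing the data, was planned, and the cause of the changes was not tested. The median absolute deviation was 0.117 to 0.167 on sevd2 arrays and 0.207 to 0.289 on sevS11 arrays. The shared spread includes that of the sevS11 extractions, which correlated at 0.451, against 0.725 for the sevd2 extractions. With scaling sevd2 had more calls than sevS11, so the counts do not rank the effects of the genotypes. The gene counts of 3, 207 and 2 for sevd2, sevS11 and their difference were 0, 162 and 1 without the dye correction, 39, 395 and 41 in the array-level fit, 11, 203 and 1 with centring, 174, 117 and 27 with scaling, 166, 145 and 23 with quantile normalisation, 51, 255 and 26 with weights, 3, 192 and 1 in a robust fit, 13, 132 and 0 for genes on every array (287 at an unadjusted p under 0.05 in the last, where PPO2 was not tested for want of a value on sevd2 replicate 3), 3, 189 and 1 per probe, 33, 408 and 24 at a threshold of 0.1 and 5, 222 and 1 with the sevS11 pair's dye effect. The sevd2 genes, 2 higher and 1 lower, split into 4 and 7 with centring, 74 and 100 with scaling and 75 and 91 with quantile normalisation, and the difference into 20 and 7 and 15 and 8 with the last 2. With only a genotype's own extractions, 497 genes passed in sevd2, 257 of them higher, and 175 in sevS11, and sev passed in sevd2 at -0.36 (limma, adjusted p = 0.0157). In the sevS11 fit sev had a limma adjusted p of 5.8e-52, though its arrays lay at 1.808, 1.895 and 4.334. That fit thus gave its genes nearly 1 common spread, and calls from 2 extractions alone are not firm. With quantile normalisation the sev difference passed at 2.35 (limma, adjusted p = 0.0173). Leaving out single arrays or extractions gave 4 to 540, 76 to 1748 and 1 to 1521 genes, with a lone extraction assumed to vary like the others. The sev ratios were then -0.41 to -0.31 in sevd2, 1.85 to 4.48 in sevS11 and 2.21 to 4.84 in the difference. The list counts of 1, 1 and 2 became 1 to 8, 1 to 5 and 2 to 7, hemocyte means -0.66 to -0.45, 0.44 to 0.68 and 0.89 to 1.34, and furrow means 0.01 to 0.10, 0.29 to 0.39 and 0.24 to 0.33. With an estimated correlation and with fry the list counts were 0, 0 and 0 (0, 0 and 0, and 1, 2 and 1, at an unadjusted p under 0.05), and hemocyte genes (-0.57 in sevd2, 1.09 in the difference) and furrow genes (0.33 in sevS11, 0.28 in the difference) did not pass. No mean of these 2 lists changed sign with centring, scaling or quantile normalisation. The counts with an estimated correlation rest on 2 residual degrees of freedom and say little. The tested members of a list could change with the arrays left out. With the extraction number as a replicate block the counts were 92, 383 and 86 genes and 2, 2 and 4 lists, and the sev difference (3.50) and the sevS11 hemocyte list (0.52) passed. Deviations of same-numbered extractions correlated at -0.065 across genes, which shows no sign of a shared batch but cannot exclude one. The correlation of the genotypes' ratios, 0.332, was 0.0910 on arrays with the mutant in Cy3, which hold no sevS11 extraction 2, 0.451 on those with it in Cy5 and 0.486 for genes with the larger mean. Named genes kept their side of the threshold in 626 cases, newly passed in 184 and no longer passed in 32, which includes the looser threshold of 0.1. With arrays or extractions left out these were 531, 169 and 18. Signal over background, which limits dim probes, was not used here.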

Other observations

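The tests in this part were chosen after the data were seen. Of 16 gene families recognised by symbol, aminoacyl-tRNA synthetases, which charge tRNAs, were lower in sevS11 with a mean of -0.19 over 17 genes and -0.26 and -0.12 in the extractions (camera, adjusted p = 0.0153, and 0.862 with an estimated correlation). Mitochondrial ribosomal proteins had a mean of 0.17 over 48 genes (adjusted p = 0.00457), respiratory complex I subunits 0.17 over 25 (adjusted p = 0.0253) and cytosolic ribosomal proteins 0.12 over 33 (adjusted p = 0.0253), each by camera. These 3 families lay above 0 in extraction 1 and below 0 in extraction 2, at 0.38 and -0.03, 0.41 and -0.06, and 0.41 and -0.18. These 3 calls were lost as well with an estimated correlation (camera, adjusted p = 0.862), a test on 2 residual degrees of freedom that hardly any family could pass. In the same order, the means of these families were 0.099, 0.096 and 0.045 with scaling and 0.111, 0.111 and 0.053 with quantile normalisation. Of 27 proteasome subunits 5 were lower in sevS11, but the family did not pass (camera, adjusted p = 0.379). No family passed in sevd2.

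Between the genotypes, cuticular proteins were higher in sevS11 by 0.18 over 12 genes (camera, adjusted p = 0.0162, and 0.918 with an estimated correlation). Their extraction means were 0.055 and 0.094 in sevS11 and -0.117 and -0.087 in sevd2. Mitochondrial ribosomal proteins (0.20), cytosolic ribosomal proteins (0.22) and complex I subunits (0.19) also passed (camera, adjusted p = 0.000639, 0.00515 and 0.0146). Their sevS11 extraction means had opposite signs, as given above. In sevd2 the extraction means of these families were -0.062 and 0.012, -0.127 and -0.078, and -0.052 and 0.021. These 3 calls were lost as well with an estimated correlation (adjusted p = 0.918).

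As a hypothesis, calls in sevS11 may follow strain differences along the chromosomes. On arm 3L 37 of 691 tested genes were lower, 5.35% against 3.22% elsewhere, with an odds ratio of 1.70 (two-sided Fisher's exact test, p = 0.0122). On the X chromosome 11 of 524 were lower, 2.1% against 3.9% elsewhere, with an odds ratio of 0.528 (two-sided Fisher's exact test, p = 0.0426). Neither passed over 10 tests of arm and direction (adjusted p = 0.122 and 0.213). Adjacent tested genes were called in 1 direction in 8 pairs, against a median of 6 in 1000 shuffles (permutation p = 0.296). These tests do not settle the question.

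A wing disc reference pool, as 1 description has it, could put eye-specific genes far above 0 in both genotypes. Over the 26 tested genes of the retinal determination, R7 and R8, photoreceptor and cone lists, some of which, such as dac, wing discs also express, the median was 0.094 in sevd2 (SD across genes 0.198) and 0.113 in sevS11 (SD 0.374). In sevd2 0 of them and in sevS11 1 lay above 1, so these ratios argue against a wing disc reference pool, a test chosen after the ratios were seen.

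Across genes, sevS11 extraction 2 correlated at 0.451 with sevS11 extraction 1 and at 0.432 and 0.36 with the sevd2 extractions. The sevd2 extractions correlated with each other at 0.725, and sevS11 extraction 1 with them at 0.166 and 0.11.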
